A study of Homo sapiens with 20 samples.

How the data were processed

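Gene expression was measured by RNA-seq of poly(A) RNA, and binding of the NF-κB subunit p65 (gene RELA) by ChIP-seq, in a line of human mammary epithelial cells immortalized with telomerase. Per the labels, cells were kept overnight without EGF-containing supplements and then left untreated or given EGF at 100 ng/mL or IL-1β at 10 ng/mL, for 4 h before RNA-seq and for 1 h before ChIP-seq. The cells for RNA-seq carried a non-targeting shRNA (shctrl) or an shRNA against p65 (shp65), which gave 12 libraries in 6 groups of 2. ChIP-seq was made in cells without an shRNA, with 2 replicates per condition. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

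The RNA-seq files held deposited gene counts, which HTSeq made per the submitters' processing notes, with TopHat2 also named there and hg19 as the genome build. Versions, the strand setting and the counting mode were not given in the sources used here, so reads shared by paralogs, overlapping genes or antisense genes could not be told apart. The submitters' processing notes also name edgeR, Bowtie2, SAMtools and MACS2. The peak files were deposited in the narrowPeak format, as 1 list per replicate and 1 merged list per condition. Each peak carried the authors' fold enrichment over background, a ratio, and the authors' −log10 of its q-value. Both were used only to describe, rank or filter peaks within a list. How the merged lists were made, the threshold of the calls and the depth of the ChIP-seq libraries were not given in the sources used here. The input DNA samples were not analysed here.

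Each count file had 25375 lines, of which 25369 were genes; the others were the counting program's summary lines and a line without a name that held 0 counts. Counts of the 12 libraries were fitted in edgeR 4.0.16 under R 4.3.3 with 1 mean per group. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 15069, and libraries were scaled by TMM factors. The quasi-likelihood test gave 10 contrasts, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. All groups shared 1 estimate of the spread because each held only 2 libraries. Standard errors (SE) of log2 fold changes were derived from the F statistic of that test, and levels are given as CPM (counts scaled to library size). Where all libraries of a group had 0 counts for a gene, the fold was left out and CPM are given, or a list's median is given with such genes at a floor of 3 counts per library.

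The contrasts were the EGF and IL-1 responses in shctrl and in shp65 cells, the knockdown effect in untreated, EGF-treated and IL-1-treated cells, the difference between shp65 and shctrl in each response, and EGF against IL-1 in shctrl cells. Genes called p65-dependent were those called in a response of shctrl cells and called with the opposite sign in the response difference. The tests, the 24 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The rule named up to 10 genes per direction with the largest change among called genes with a mean of at least 1 CPM, whose libraries did not overlap between the 2 groups where a contrast had 2. It also named RELA and, per list, the 4 members with the smallest p. A smaller selection of these is described.

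The lists were NF-κB pathway genes and feedback inhibitors, chemokines, cytokines and colony-stimulating factors, adhesion molecules and immune receptors, apoptosis antagonists, antimicrobial and acute-phase genes, interferon-stimulated genes, immediate-early and AP-1 transcription factors, ERK feedback regulators, EGF family ligands, proteases with plasminogen system and migration genes, squamous differentiation genes, cholesterol synthesis and uptake genes, ribosome biogenesis genes, cell cycle genes, FOXO and quiescence-associated genes, mesenchymal transition genes, heat shock and stress genes, and mitochondrially encoded genes. Lists of basal and luminal markers stood for mammary epithelial cells, and lists of fibroblast, immune cell and endothelial markers for other cell types. All lists together held 447 genes that were tested, 8 of them in more than 1 list. Each list with at least 3 tested members was tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry.

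RELA levels were compared with an exact two-sided permutation test over all splits of the libraries into 6 and 6. The overlap of both responses was set beside 20 simulations in which no group changed, since both used the same untreated libraries. Peak lists were compared with bedtools 2.31.1 under Python 3.11.15, and peaks that shared at least 1 bp counted as shared. The peak coordinates are those of hg19. A test of peaks near responding genes was not run, because no annotation of that build was used here.

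The tests were tested on simulated data with 200 genes changed by known factors. For the EGF response in shctrl cells, 40 of 67 genes changed 2-fold and 55 of 66 changed 4-fold were recovered, with 7 false calls among 14778 genes tested. For the knockdown effect in untreated cells, 32 of 67 and 54 of 66 were recovered, with 4 false calls among 14801 genes. For the EGF response difference, 9 of 67 and 43 of 66 were recovered. For the IL-1 response difference, 21 of 67 and 51 of 66 were recovered. Of genes changed 1.5-fold, 5 of 67 were recovered for the EGF response in shctrl cells and 8 of 67 for the knockdown effect. For each response difference it was 1 of 67. The simulated genes were independent, and their spread was the one the model had estimated, equal in all groups. The real replicate pairs differed in spread between groups. The simulated false calls and recovery therefore do not give those of the real comparisons.

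The alternatives were RLE factors (DESeq2's size factors) or library totals in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, each library left out in turn, an estimated correlation for the gene lists, and, for peaks, a −log10 q of at least 5, 1 replicate in place of the merged list, only merged peaks found in both replicates, and 50% reciprocal overlap. A fit without the 4 libraries whose RELA level went against their label was chosen after the data were seen.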

Results

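RNA-seq counts were available for 12 libraries of immortalized human mammary epithelial cells, 2 in each of 6 groups, and p65 ChIP-seq peak lists for 3 conditions with 2 replicates each. RNA depth ranged from 18.3 to 30.5 M gene counts per library. In replicates 1 and 2, it was 22.5 and 22.2 M in untreated shctrl cells, 29.1 and 27.6 M in the libraries labelled shctrl EGF, and 30.5 and 25.6 M in the libraries labelled shctrl IL-1. It was 18.3 and 27.4 M in untreated shp65 cells, 25.9 and 20.1 M in the libraries labelled shp65 EGF, and 27.6 and 26.0 M in the libraries labelled shp65 IL-1. No pair of replicates was identical, and each pair differed by more than sampling noise, with a chi-square per degree of freedom from 13.5 to 85.3. The study asked which genes and p65 binding sites respond to EGF or IL-1 in a way that depends on p65.

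RELA, the gene that the shRNA targets and that encodes p65, did not follow the labels in 4 of the 12 libraries. RELA stood at 76.8 and 73.4 CPM in the untreated shctrl libraries and at 23.4 and 29.4 CPM in the untreated shp65 libraries. It stood at 89.9 and 87.4 CPM in the libraries labelled shctrl EGF, but at 42.3 and 35.3 CPM in those labelled shctrl IL-1. In the libraries labelled shp65 EGF it was the highest of all groups, at 104.8 and 100.7 CPM, and in those labelled shp65 IL-1 it was 38.8 and 31.9 CPM. Over all libraries RELA averaged 54.9 ± 37.5 CPM (SD, n = 6) in shp65 and 67.5 ± 23.2 CPM (SD, n = 6) in shctrl libraries (exact two-sided permutation p = 0.504, 924 splits). The SDs and this test pool all treatments, and the libraries of a group lay close together by comparison. That p therefore does not measure the spread between replicates. The knockdown contrast of RELA was a log2 fold change of −1.50 ± 0.15 (SE) in untreated cells (edgeR adjusted p = 0.00203), 0.21 between the groups labelled EGF (adjusted p = 0.269) and −0.13 between the groups labelled IL-1 (adjusted p = 0.501). The groups were kept as labelled. Comparisons of the EGF response in shctrl cells, the IL-1 response in shp65 cells and the knockdown effect in untreated cells hold none of the 4 libraries in their contrast, although these share the estimate of the spread.

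**Figure D1:**
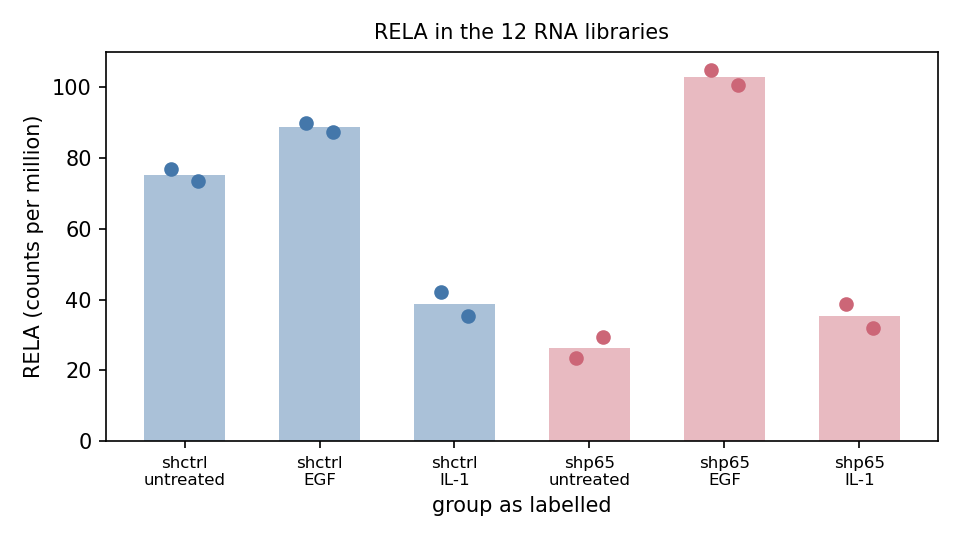
RELA in counts per M (vertical axis) for the 6 groups as labelled (horizontal axis); bars are means of 2 libraries and points are the libraries. The libraries labelled shp65 EGF reached 104.8 and 100.7 CPM, above every shctrl library, and those labelled shctrl IL-1 stood at 42.3 and 35.3 CPM.

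Knockdown of p65 in untreated cells lowered a small number of genes of the NF-κB pathway, proteases and ribosome biogenesis. MMP1, an interstitial collagenase, fell by 3.47 ± 0.37 (log2, SE; adjusted p = 0.00294), IL1B changed by −2.75 ± 0.47 (adjusted p = 0.0183) and TNFAIP3, a feedback inhibitor of NF-κB, by −2.30 ± 0.37 (adjusted p = 0.0155). SERPINB3, a serpin of squamous epithelia, changed by −3.36 and SLC39A14, a zinc transporter, by −2.44. SPOCK3 was 3.30 ± 0.27 higher on the log2 scale, LIPH 3.16 and LPHN3 4.18. Of 24 NF-κB pathway genes, 5 fell, and the same number fell adjusted over the list alone. These included NFKBIA, which encodes the inhibitor IκBα (log2 fold change −0.96), and RELB (−1.05) and TRAF3 (−0.89). The camera test of that list gave adjusted p = 0.000374, and adjusted p = 0.448 with an estimated correlation. Among 28 protease and migration genes, 4 fell (8 adjusted over the list alone), including MMP10 (−1.88); the list had adjusted p = 5.99e-05, and adjusted p = 0.448 with an estimated correlation. Of 32 ribosome biogenesis genes, 7 fell, among them NOP2 (−0.90) and DDX21 (−0.76), and 26 fell adjusted over the list alone. That list had a median log2 fold change of −0.48 and adjusted p = 2.57e-17, and adjusted p = 0.181 with an estimated correlation. Among 8 EGF family ligands, EREG (−0.99) and HBEGF (−1.43) fell, as they did adjusted over the list alone. Of 24 cytokines 1 was higher and 2 lower (2 and 6 adjusted over the list alone; adjusted p = 0.000409, and adjusted p = 0.448 with an estimated correlation). Of 11 chemokines edgeR called 0, over all genes and adjusted over the list alone, with 5 lower at an unadjusted p under 0.05 and 0 by DESeq2. Of 18 adhesion molecules it called 0, likewise over the list alone, with 2 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. Of 15 antimicrobial and acute-phase genes 0 were higher and 2 lower (1 and 9 adjusted over the list alone; adjusted p = 0.00048, and adjusted p = 0.448 with an estimated correlation). Of 12 fibroblast markers edgeR called 0, likewise over the list alone, with 4 lower at an unadjusted p under 0.05 and 0 by DESeq2. Their median was −0.67 (adjusted p = 0.0402, and adjusted p = 0.719 with an estimated correlation). The calls of NFKBIA, RELB, TRAF3, TNFAIP3, IL1B, MMP10, NOP2, DDX21, EREG, HBEGF, LIPH and LPHN3 were lost without shctrl untreated replicate 2. Those of NFKBIA, RELB, TRAF3, TNFAIP3, IL1B, MMP10, DDX21, EREG, HBEGF and SERPINB3 were lost without shp65 untreated replicate 2. Without its replicate 1, EREG, MMP10, RELB and TNFAIP3 were lost, and HBEGF without shctrl untreated replicate 1. Leaving out either library labelled shp65 EGF lost EREG, HBEGF, MMP10, RELB and TRAF3, and either labelled shctrl IL-1 lost HBEGF and MMP10. The fit without all 4 of these libraries lost NFKBIA, RELB, TRAF3, MMP10, NOP2, DDX21, EREG and HBEGF. The highest adjusted p of these genes over all alternatives ranged from 0.068 for SERPINB3 to 0.224 for TRAF3. The calls of MMP1, SLC39A14 and RELA were lost only in a fit of the 4 untreated libraries alone (adjusted p = 0.068 for each), and that of SPOCK3 in no alternative run.

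In all, 130 genes were higher and 194 lower in untreated shp65 than in untreated shctrl cells. With library totals in place of TMM the split was 182 higher and 168 lower. These counts rested on single libraries. They fell to 7 and 16 without shctrl untreated replicate 2, and to 39 and 24 without shp65 untreated replicate 2. They were 25 and 20 without the 4 libraries whose RELA went against the label, all 45 among the genes first called. Leaving out 1 library labelled shctrl IL-1 gave 54 and 60 for either replicate, and leaving out 1 labelled shp65 EGF gave 47 and 53. Without shctrl EGF replicate 1 or 2, 227 or 225 genes were higher. Without shp65 IL-1 replicate 1 the lower count was 101, and without replicate 2 the counts were 80 and 102. A fit of the 4 libraries alone called 1 gene higher and 0 lower with edgeR, where 822 and 715 had an unadjusted p under 0.05. The replicate pairs of this contrast differed most, with a chi-square per degree of freedom of 85.3 (shctrl) and 48.1 (shp65). In the other groups it ran from 13.5 to 47.4. The estimate of the spread shared by all groups may therefore be too small here, and the counts of the main fit too high, which was not tested. DESeq2, run on all 12 libraries, called 325 and 450.

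EGF in shctrl cells raised ERK feedback regulators, growth factor ligands and biosynthetic genes, and lowered FOXO-associated genes. SPRY4, an inhibitor of receptor tyrosine kinase signaling, rose by 4.73 ± 0.36 on the log2 scale (SE; adjusted p = 3.77e-06), HAS2, a hyaluronan synthase, by 5.57 ± 0.55 (adjusted p = 1.76e-05) and LRP8, a lipoprotein receptor, by 4.36 ± 0.21 (adjusted p = 6.76e-07). ADRA1D rose by 5.85 and CSF3, which encodes the growth factor G-CSF, by 4.66. PDK4, an inhibitor of pyruvate dehydrogenase, changed by −7.11 ± 0.86 (adjusted p = 6.64e-05), ZBTB16 by −7.43 and CYP1A1 by −5.79. All these genes had both EGF libraries on the same side of both untreated libraries, which the naming rule required of the genes with the largest changes. Of 32 ribosome biogenesis genes, 30 rose and 0 fell, the same adjusted over the list alone, with NOP56 at 2.24, NOP2 at 2.10 and DDX21, a nucleolar helicase, at 2.54. The list had adjusted p = 1.76e-32 in camera, and adjusted p = 0.0354 with an estimated correlation. Of 29 FOXO and quiescence-associated genes, 27 fell (28 adjusted over the list alone) and 0 rose, among them PIK3IP1, an inhibitor of PI3-kinase (−2.84), KLHL24 (−3.07) and GABARAPL1 (−3.22). This list had adjusted p = 5.43e-28, and adjusted p = 0.0901 with an estimated correlation. Of 26 cholesterol genes, 21 rose and 0 fell, the same adjusted over the list alone, with HMGCS1 at 3.50, SQLE at 2.20 and CYP51A1 at 2.00 (adjusted p = 1.32e-10, and adjusted p = 0.383 with an estimated correlation).

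ERK feedback regulators had 13 of 23 genes higher and 2 lower after EGF, the same adjusted over the list alone, including DUSP4, a phosphatase of ERK (2.31), ERRFI1 (1.92) and PHLDA1 (2.43); camera gave adjusted p = 0.00011, and adjusted p = 0.258 with an estimated correlation. Among 8 EGF family ligands 5 rose and 0 fell, the same adjusted over the list alone, with NRG1 at 3.09 and TGFA at 3.16 (adjusted p = 0.000307, and adjusted p = 0.128 with an estimated correlation). Heat shock and stress genes had 15 of 20 higher and 3 lower, the same adjusted over the list alone, with HSPD1 at 2.04 and HSPA1A, which has the near-identical copy HSPA1B, at 2.82 (adjusted p = 6.77e-08, and adjusted p = 0.128 with an estimated correlation). Among 28 protease and migration genes 15 rose and 4 fell, the same adjusted over the list alone, with MMP1 at 3.07 and PLAUR, the urokinase receptor, at 2.41, while TIMP3 fell by 2.65 (adjusted p = 0.0108, and adjusted p = 0.639 with an estimated correlation). Cell cycle genes had 15 of 35 higher and 1 lower, the same adjusted over the list alone, with E2F1 at 4.31 and UHRF1 at 3.51 (adjusted p = 0.00274, and adjusted p = 0.737 with an estimated correlation). Squamous differentiation genes had 4 of 25 higher and 13 lower, the same adjusted over the list alone. ELF3, an epithelial transcription factor, changed by −5.03 and OVOL1 by −5.45, while the keratin KRT6B rose by 2.71 (adjusted p = 0.0254, and adjusted p = 0.527 with an estimated correlation).

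The inflammatory lists went both ways after EGF, as did all 15069 genes tested, of which 47.2% were called (3610 higher and 3505 lower). Of 24 NF-κB pathway genes 4 rose and 6 fell, the same adjusted over the list alone, with NFKBIA at −0.89, REL at −2.02 and MAP3K8 at −3.26; the median was 0.14, the mean −0.13 and the camera adjusted p = 0.596. Of 11 chemokines 5 rose and 1 fell (5 and 2 adjusted over the list alone), with CXCL8 at 3.34 and CXCL1 at 2.78; the median was −0.55, the mean 0.35 and adjusted p = 0.207. Counts of genes higher and lower, over all genes and adjusted over the list alone, were 7 and 5 in both for 24 cytokines, 8 and 3 in both for 18 adhesion molecules, and 10 and 6 in both for 26 immediate-early factors. They were 5 and 5 for 14 apoptosis antagonists (5 and 6 adjusted over the list alone), 3 and 4 for 15 antimicrobial genes (3 and 3) and 2 and 7 for 29 interferon-stimulated genes (1 and 6). Among the cytokines IL1B rose by 2.86, among the immediate-early factors FOSL1 rose by 2.86 and KLF4 fell by 3.52, and among the interferon-stimulated genes STAT2 fell by 1.59. The camera adjusted p of these 6 lists lay between 0.207 and 0.911. The mean and median differed in sign for immediate-early factors (−0.02 and 0.32) and antimicrobial genes (0.14 and −0.43), and for apoptosis antagonists the test pointed down with a median of 0.65. Mesenchymal transition genes had 4 higher and 3 lower of 18, basal markers 0 and 5 of 14 with KRT15 at −4.65, luminal markers 2 and 3 of 12, fibroblast markers 1 and 1 of 12, immune cell markers 0 and 1 of 5, and endothelial markers 0 and 4 of 7. Adjusted over the list alone these were 4 and 3, 0 and 5, 1 and 3, 1 and 0, 0 and 0, and 0 and 4. Their camera adjusted p lay between 0.126 and 0.713. None of the 13 mitochondrially encoded genes was among the genes tested.

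In all, 3610 genes rose and 3505 fell after EGF in shctrl cells. With library totals in place of TMM 2795 rose and 4313 fell, and the median of all genes stood at −0.19 in place of −0.04 (log2). Without the 4 libraries whose RELA went against the label, 3079 rose and 2978 fell, with 6041 genes called in the same direction in both fits.

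The libraries labelled shctrl IL-1, in which RELA went against the label, had higher ribosome biogenesis genes and ERK feedback regulators and lower FOXO-associated genes than untreated shctrl cells. RELA itself was lower by −0.95 ± 0.15 on the log2 scale (SE; adjusted p = 0.000366). SPRY4 was 4.86 ± 0.37 higher (adjusted p = 5.2e-06), IL1RL1, the receptor of IL-33, 6.43 ± 0.71 (adjusted p = 4.01e-05), LRP8 4.04 and CXCL8, a neutrophil chemokine, 4.04. PDK4 changed by −6.99 ± 0.84 (adjusted p = 7.36e-05), ACKR3 by −5.64 and BMF, a pro-apoptotic factor, by −5.26. Of 24 NF-κB pathway genes 4 were higher and 8 lower, the same adjusted over the list alone, with NFKBIA at −1.35 and MAP3K8 at −3.57 (camera adjusted p = 0.416). The acute-phase genes C3 (−4.33) and CFB (−2.74) and the mitochondrial dismutase SOD2 (−1.19) were lower. Of 32 ribosome biogenesis genes 30 were higher and 0 lower, the same adjusted over the list alone, with DDX21 at 2.42 and RRS1 at 3.00 (adjusted p = 2.8e-27, and adjusted p = 0.0549 with an estimated correlation). Of 29 FOXO and quiescence-associated genes 26 were lower and 0 higher, the same adjusted over the list alone, with PIK3IP1 at −2.24 (adjusted p = 1.21e-19, and adjusted p = 0.16 with an estimated correlation). ERK feedback regulators had 14 of 23 higher and 2 lower (16 and 2 adjusted over the list alone), with DUSP4 at 2.41 and DUSP6 at 2.13 (adjusted p = 2.2e-06, and adjusted p = 0.162 with an estimated correlation). Interferon-stimulated genes had 3 of 29 higher and 13 lower, the same adjusted over the list alone, with IFIT2 at −3.86 (adjusted p = 0.0287, and adjusted p = 0.267 with an estimated correlation). Cell cycle genes had 9 of 35 higher and 4 lower, the same adjusted over the list alone (adjusted p = 0.702), and squamous differentiation genes 4 of 25 higher and 8 lower, the same adjusted over the list alone (adjusted p = 0.419). Of 7 endothelial markers 4 were lower and 0 higher, the same adjusted over the list alone (adjusted p = 0.0879), and of 12 fibroblast markers 1 was higher and 4 lower (1 and 6 adjusted over the list alone; adjusted p = 0.305).

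In all, 3601 genes were higher and 3377 lower in the libraries labelled shctrl IL-1 than in untreated shctrl libraries. Without shctrl IL-1 replicate 1 the lower count was 2110.

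The EGF libraries and the libraries labelled shctrl IL-1 shared 2972 genes higher and 2646 lower against the same untreated libraries, and 12 genes went in opposite directions. Independent lists of these sizes would share 863 and 786, and 20 simulations with no change shared 0, which their near absence of calls fixed in advance. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.858 against 0.512 in the simulations, and 87.5% had the same sign against 66.9%. Their covariance was 0.967 against 0.0518, a difference of 0.915. A split of the 2 untreated libraries would leave 1 per comparison and was not run, so part of the excess of shared genes over independent lists may come from sharing them. The difference in covariance sets aside what the simulations attribute to sharing. All these values hold for groups as labelled. If the labels shctrl IL-1 and shp65 EGF were exchanged, both responses would be to EGF, and the overlap would not compare 2 ligands. On the log CPM scale, the libraries labelled shctrl IL-1 correlated with those labelled shctrl EGF at 0.980 to 0.988. The 2 shctrl EGF replicates correlated with each other at 0.985.

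EGF against the libraries labelled shctrl IL-1, a direct test of ligand specificity if the labels hold, gave 63 genes higher and 167 lower. RELA was 1.19 ± 0.15 higher with EGF (log2, SE; adjusted p = 0.00546), although both groups are labelled with the control shRNA. The complement gene C3 was 3.37 ± 0.54 higher (adjusted p = 0.0144), PTX3 3.31 ± 0.52 (adjusted p = 0.0124) and TNFAIP3 2.22 ± 0.36 (adjusted p = 0.0158). The C3 difference was 1.82 without shctrl EGF replicate 2 and 4.12 without its replicate 1. SPOCK3 was lower by −3.21 ± 0.28 (adjusted p = 0.00133), LIPH by −3.09 and LPHN3 by −6.71. Cell cycle genes had 0 of 35 called by edgeR over all genes, 22 higher and 0 lower at an unadjusted p under 0.05, 5 higher by DESeq2 on all 12 libraries and 19 higher adjusted over the list alone, with a median of 0.95 (camera adjusted p = 4.15e-13, and adjusted p = 0.472 with an estimated correlation). FOXO and quiescence-associated genes had 4 of 29 lower (11 adjusted over the list alone; adjusted p = 2.57e-08, and adjusted p = 0.472 with an estimated correlation). Without shctrl IL-1 replicate 2, edgeR called 0 genes higher and 10 lower, with 432 and 610 at an unadjusted p under 0.05, and RELA, C3, PTX3, TNFAIP3, LIPH and LPHN3 were no longer called (highest adjusted p over all alternatives from 0.0713 to 0.228); C3 was also lost without shctrl IL-1 replicate 1, which left 25 genes higher. Leaving out shctrl EGF replicate 1 or 2 gave 105 or 104 higher, and 71 lower without replicate 2. Leaving out shp65 EGF replicate 1 or 2 gave 38 or 40 higher and 82 or 93 lower, and shp65 IL-1 replicate 1 or 2 gave 105 or 102 lower. A fit of the 4 libraries alone called 0 higher and 5 lower with edgeR, with 831 and 1021 at an unadjusted p under 0.05. DESeq2, run on all 12 libraries, called 199 and 376.

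IL-1 in shp65 cells, where RELA followed the label in both groups, raised NF-κB targets. CXCL8 rose by 7.28 (log2; adjusted p = 3.98e-08), CXCL1 by 5.66 (adjusted p = 3.73e-06) and SOD2 by 3.78 (adjusted p = 1.08e-06). SERPINB3 rose by 5.69 and ELF3 by 4.01. Of 24 NF-κB pathway genes 15 rose and 0 fell (19 and 1 adjusted over the list alone), with TNFAIP3 at 3.63 and NFKBIA at 2.26; camera gave adjusted p = 3.92e-24, and adjusted p = 0.00788 with an estimated correlation. Of 11 chemokines 5 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 6.25e-47, and adjusted p = 0.00255 with an estimated correlation). Their median was 4.50, and 1.67 with genes absent from a group at the floor. CCL20 stood at 0 in both untreated shp65 libraries and at 20.4 and 9.86 CPM after IL-1. Of 24 cytokines 15 rose and 0 fell (16 and 0 adjusted over the list alone), with IL6 at 3.56 (adjusted p = 4.23e-21, and adjusted p = 0.0339 with an estimated correlation). IL6 was not called without shp65 untreated replicate 2 or shp65 IL-1 replicate 1 (adjusted p up to 0.0948, against 0.00943). Squamous differentiation genes had 14 of 25 higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 1.6e-26, and adjusted p = 0.00788 with an estimated correlation). Antimicrobial and acute-phase genes had 10 of 15 higher and 1 lower (11 and 1 adjusted over the list alone), with CFB at 2.77 (adjusted p = 4.21e-16, and adjusted p = 0.0241 with an estimated correlation). Apoptosis antagonists had 5 of 14 higher and 1 lower (6 and 2 adjusted over the list alone; adjusted p = 5.75e-09, and adjusted p = 0.0081 with an estimated correlation). ERK feedback regulators had 4 of 23 higher and 5 lower (4 and 8 adjusted over the list alone), with DUSP4 at −1.21 (adjusted p = 0.208).

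In all, 684 genes rose and 224 fell after IL-1 in shp65 cells. With library totals the split was 490 and 323, with the median of all genes at −0.12. Without the 4 libraries whose RELA went against the label, 263 rose and 35 fell, all 298 among the genes first called. The counts were 117 and 6 without shp65 IL-1 replicate 1, 408 and 98 without its replicate 2, and 194 and 47 without shp65 untreated replicate 2. They were 419 and 102 without shp65 EGF replicate 1 and 419 and 101 without its replicate 2. The lower count was 376 or 374 without shctrl EGF replicate 1 or 2, and 138 or 141 without shctrl IL-1 replicate 1 or 2.

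The libraries labelled shp65 EGF, in which RELA went against the label (1.96 ± 0.15 higher than in untreated shp65 cells on the log2 scale, SE; adjusted p = 1.41e-05), had high levels of NF-κB and interferon-stimulated genes. CXCL8 was 7.93 higher (adjusted p = 1.86e-08), SOD2 5.47 (adjusted p = 6.04e-08) and ICAM1, a leukocyte adhesion molecule, 3.30 (adjusted p = 9.93e-07). Of 29 interferon-stimulated genes all 29 were higher, also adjusted over the list alone, with MX1 at 6.63 and IFIH1, a sensor of double-stranded RNA, at 3.45 (camera adjusted p = 4.91e-64, and adjusted p = 0.000509 with an estimated correlation). Of 24 NF-κB pathway genes 19 were higher and 2 lower, the same adjusted over the list alone, with TNFAIP3 at 5.72 and NFKBIA at 3.15 (adjusted p = 8.75e-22, and adjusted p = 0.00717 with an estimated correlation). Of 11 chemokines 10 were higher and 0 lower, the same adjusted over the list alone (adjusted p = 3.61e-41, and adjusted p = 0.00165 with an estimated correlation). CXCL10 stood at 0 in both untreated shp65 libraries, at 47.7 and 50.4 CPM in those labelled shp65 EGF and at 0.580 and 0.225 CPM in those labelled shp65 IL-1. Ribosome biogenesis genes had 13 of 32 higher and 0 lower (14 and 0 adjusted over the list alone), with DDX21 at 0.88 (adjusted p = 0.00193, and adjusted p = 0.352 with an estimated correlation). FOXO and quiescence-associated genes had 2 of 29 higher and 8 lower (2 and 10 adjusted over the list alone; adjusted p = 0.00331, and adjusted p = 0.481 with an estimated correlation), and ERK feedback regulators 6 of 23 higher and 9 lower (8 and 9 adjusted over the list alone; adjusted p = 0.887). In all, 2260 genes were higher and 1785 lower, and 1558 and 3005 with library totals, with the median of all genes at −0.205 in the latter. The counts were 1243 and 691 without shp65 EGF replicate 1 and 1197 and 676 without its replicate 2.

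**Figure D2:**
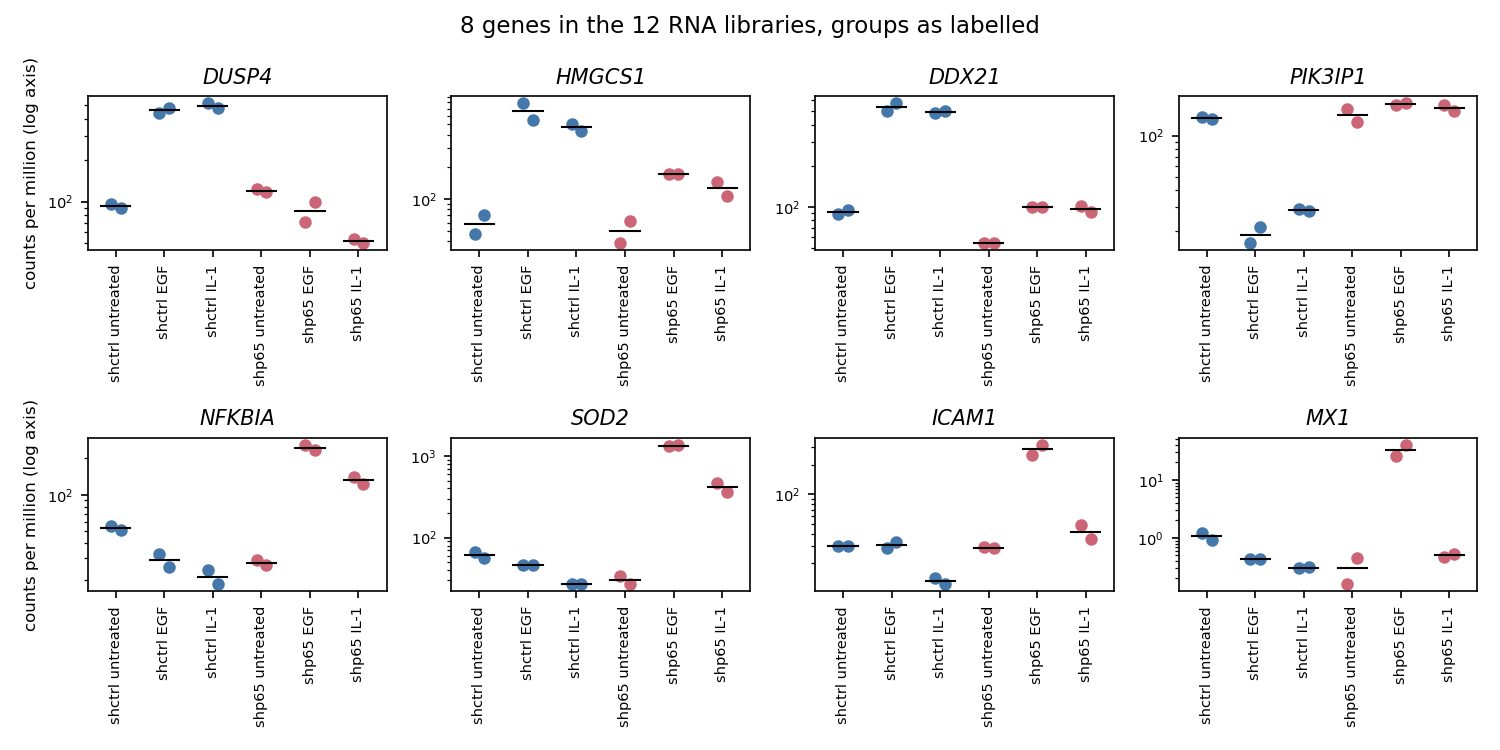
Counts per M on a log axis for 8 genes in the 6 groups as labelled; points are libraries and lines are means of 2. DDX21 stood at 506.6 and 570.6 CPM in the libraries labelled shctrl EGF and at 100.8 and 100.3 CPM in those labelled shp65 EGF, and MX1 at 26.3 and 40.3 CPM in the latter.

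The responses were compared between shp65 and shctrl cells to ask which of them depend on p65. Both comparisons hold libraries whose RELA went against the label, so their direction holds only for groups as labelled. The response labelled EGF differed in 1794 genes that were higher and 1572 that were lower in shp65 cells. SOD2 differed by 5.88 ± 0.25 (log2, SE; adjusted p = 6.79e-07), CFB by 8.35 ± 0.59 (adjusted p = 1.1e-05) and MX1 by 7.94, while DUSP4 differed by −2.80 and DDX21 by −1.66. Higher lists included interferon-stimulated genes (25 of 29, and 27 adjusted over the list alone; camera adjusted p = 1.53e-41, and adjusted p = 0.000866 with an estimated correlation) and NF-κB pathway genes (18 of 24 with 1 lower, the same adjusted over the list alone; adjusted p = 1.5e-16, and adjusted p = 0.0173 with an estimated correlation). Ribosome biogenesis genes had 29 of 32 lower (31 adjusted over the list alone; adjusted p = 1.99e-23, and adjusted p = 0.0173 with an estimated correlation). The response labelled IL-1 differed in 1544 genes that were higher and 1540 that were lower in shp65 cells. ELF3 differed by 8.11 ± 0.42 (adjusted p = 3.03e-06) and NFKBIA by 3.61, while SPRY4 differed by −4.48 ± 0.50 (adjusted p = 0.000261) and ETV5 by −3.39. NF-κB pathway genes had 13 of 24 higher and 0 lower (14 and 1 adjusted over the list alone; adjusted p = 3.05e-11, and adjusted p = 0.05 with an estimated correlation), and ribosome biogenesis genes had 27 of 32 lower (31 adjusted over the list alone; adjusted p = 5.61e-20, and adjusted p = 0.05 with an estimated correlation). Leaving out shp65 EGF replicate 1 or 2 lowered the counts for EGF to 1110 and 1024 or to 1033 and 985. Leaving out a library labelled shctrl IL-1 or shp65 IL-1 lowered those for IL-1 to between 877 and 974 higher and between 956 and 1017 lower.

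By these tests, with groups as labelled, 2591 genes were p65-dependent for EGF, 1301 of them higher and 1290 lower with EGF, which was 36.4% of the genes called in shctrl cells. For IL-1 there were 2807, 1461 higher and 1346 lower, or 40.2%. The response difference subtracts the shctrl response, so error in the shctrl libraries pushes both tests of a ligand towards opposite signs. Part of each count may come from this. With the knockdown effect under the ligand in place of the response difference the counts were 4572 and 4776. Both ligands shared 1950 in the same direction, 1010 higher and 940 lower, where independent lists would share 126 and 115. The simulations called 0 p65-dependent genes for either ligand and so shared 0, and both lists use the same untreated libraries, so neither value measures a shared effect. The EGF count rests on the libraries labelled shp65 EGF (RELA at 104.8 and 100.7 CPM) and the IL-1 count on those labelled shctrl IL-1 (RELA at 42.3 and 35.3 CPM), so neither is a count of genes that depend on p65 unless these labels hold. Without shp65 EGF replicate 1 or 2 the EGF count was 1670 or 1588. The IL-1 count was 1650 or 1802 without shctrl IL-1 replicate 1 or 2, and 1794 or 1748 without shp65 IL-1 replicate 1 or 2. The direct knockdown contrast between the groups labelled EGF called 2947 genes higher and 3036 lower, and between those labelled IL-1 2911 and 3167. In the latter the counts were 1855 and 2055 without shp65 IL-1 replicate 2, and the higher count was 1725 without shctrl IL-1 replicate 1. RELA differed by 0.21 and −0.13 in these contrasts, against −1.50 in untreated cells, so they hold for groups as labelled.

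The merged p65 peak lists held 1589 peaks in untreated cells, 2066 after EGF and 6453 after IL-1. Of the EGF peaks, 94.3% overlapped an IL-1 peak (1949) and 40.3% an untreated peak (832). Of the IL-1 peaks, 28.7% overlapped an EGF peak (1849) and 16.1% an untreated peak (1041). Of the untreated peaks, 54.6% overlapped an EGF peak (867) and 68.8% an IL-1 peak (1093). Peaks in no other merged list numbered 490 in untreated cells, 111 after EGF and 4398 after IL-1. By the authors' fold enrichment, the top IL-1 peak lay on chromosome 14 from 94811946 to 94813227 (hg19; 32.4-fold), followed by a peak on chromosome 11 from 76401741 to 76402300 (30.4-fold). The top EGF peaks lay on chromosome 3 from 136612674 to 136613103 and on chromosome 20 from 14826010 to 14826517 (both 23.6-fold). The top untreated peak lay on chromosome 14 from 96735185 to 96735698 (22.3-fold). Each of the peaks named here, of all conditions, overlapped a peak of both other merged lists, so none was particular to its condition. All these peaks were present in both replicate lists of their condition. Genes near them were not assigned, as no annotation of the build was used.

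The greater length of the IL-1 list rested on replicate 1. Replicates 1 and 2 held 721 and 231 peaks in untreated cells, 1095 and 519 after EGF, and 9750 and 486 after IL-1, so that in replicate 2 the IL-1 list was shorter than the EGF list. Merged peaks found in both replicate lists numbered 144, 367 and 417. Of the 490 merged untreated peaks in no other list 15 were in both replicates, of the 111 merged EGF peaks 0 were, and of the 4398 merged IL-1 peaks 17 were. Of the peaks of IL-1 replicate 2, 89.5% overlapped replicate 1, against 69.7% for EGF and 56.7% for untreated cells, by an overlap of at least 1 bp. IL-1 went from the highest to the lowest share with 50% reciprocal overlap, which left 12 shared peaks of 486 for IL-1, 200 of 519 for EGF and 74 of 231 for untreated cells. IL-1 replicate 1 had a median peak width of 302 bp, against 114 bp in replicate 2, and nested peaks of these widths fail 50% reciprocal overlap. The medians lay further apart in untreated cells, at 123 and 418 bp, so width is not shown to account for the low share of IL-1. The overlap of EGF with IL-1 peaks also rested on replicate 1: 95.8% of EGF replicate 1 peaks overlapped IL-1 replicate 1 and 28.9% IL-1 replicate 2, and of EGF replicate 2 peaks 99.6% and 49.9% did. Untreated peaks lay on unplaced sequences or the mitochondrial genome in 108 cases (6.80%), against 6 after EGF and 32 after IL-1. Of these 108, 88 were among the 490 untreated peaks in no other list. The merged lists have no replicates, so their lengths were not tested, and the depth behind them is unknown.

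**Figure D3:**
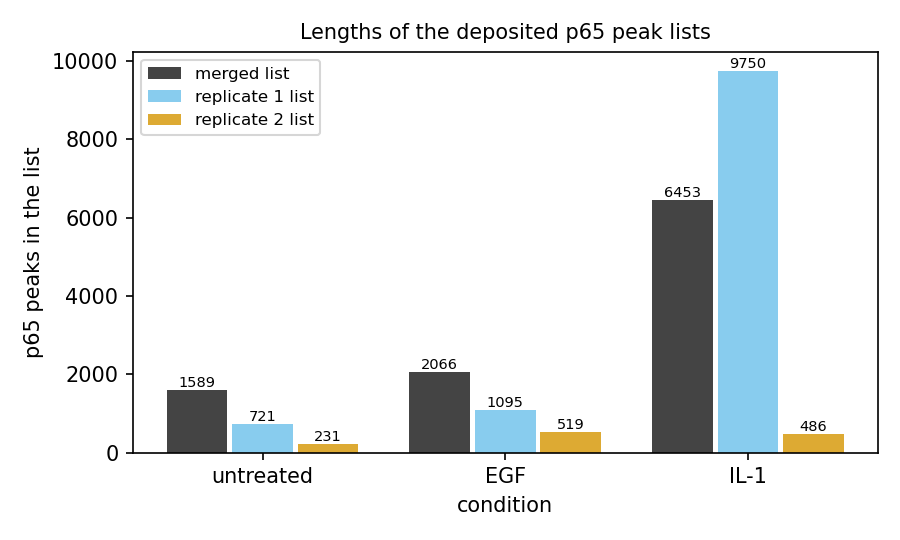
Number of p65 peaks (vertical axis) in the merged list and in each replicate list, for 3 conditions (horizontal axis). IL-1 replicate 1 had 9750 peaks, and IL-1 replicate 2 had 486, below EGF replicate 2 with 519.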

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

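The tests of explanations in this part were chosen only after the RELA levels were seen; the tests of response differences were planned.

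The response to a ligand differed between shp65 and shctrl libraries, by a test of the difference itself in edgeR, in 1794 genes higher and 1572 lower for the groups labelled EGF and in 1544 higher and 1540 lower for the groups labelled IL-1. RELA itself was among them, with a log2 difference of 1.72 (adjusted p = 0.000249) for EGF and 1.37 (adjusted p = 0.00131) for IL-1. For EGF, the differences were 9.10 for ELF3, 8.35 for CFB, 7.94 for MX1, 5.88 for SOD2, 4.59 for CXCL8, 4.53 for IFIH1, 4.27 for GABARAPL1, 4.04 for NFKBIA, 3.27 for ICAM1 and 3.11 for PIK3IP1. They were −4.67 for TLR4, −3.53 for ETV5, −2.80 for DUSP4 and −1.66 for DDX21. For IL-1, the differences were 8.11 for ELF3, 7.10 for MMP9, 6.95 for SAA2, 4.97 for SOD2, 3.61 for NFKBIA and 3.25 for CXCL8. They were −4.48 for SPRY4, −4.39 for TLR4, −3.62 for DUSP4 and −3.39 for ETV5.

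RELA went against the label in the libraries labelled shctrl IL-1 and shp65 EGF. Loss of the knockdown in the libraries labelled shp65 EGF alone is argued against, since RELA was also lower by −0.95 (log2) in those labelled shctrl IL-1, and since 5983 genes were called between the libraries labelled shp65 EGF and shctrl EGF, which such a loss alone would make alike, against 324 in the untreated knockdown comparison. A candidate explanation is that the labels of these groups were exchanged with each other: 96.0% of the 323 genes called in the untreated knockdown comparison, RELA aside, had the same sign in labelled shctrl IL-1 minus labelled shctrl EGF, and 94.4% in labelled shp65 IL-1 minus labelled shp65 EGF, in libraries which that comparison does not use. Of the 323 genes, 79 and 131 were also called with that sign in these 2 differences. Over all genes the 2 differences correlated with the knockdown effect at 0.53 and 0.52. A further test could not decide. Of the genes called in the EGF response, 66.3% had the same sign in labelled shp65 EGF minus labelled shp65 IL-1. This lay between the bounds of 60 and 75 that had been set for and against an exchange. Under an exchange that difference compares the shRNAs in IL-1-treated cells. Knockdown in untreated cells also changed EGF response genes, against EGF for MMP1 (−3.47 and 3.07) and with it for NFKBIA (−0.96 and −0.89). The share that an exchange predicts is therefore not known. By RELA and its targets alone, a response of these genes to a ligand that depends on the shRNA cannot be told apart from an exchange. Both predict higher RELA in the libraries labelled shp65 EGF (1.96). Targets that follow RELA would also give the 96.0% and 94.4%. In labelled shctrl EGF, 13 of 23 ERK feedback regulators were higher and 2 lower, and in labelled shctrl IL-1 14 and 2. They were 6 and 9 in labelled shp65 EGF and 4 and 5 in labelled shp65 IL-1. An exchange would give this, as it puts the first 2 groups under EGF and the others under IL-1. Targets that follow RELA give no reason for it. The grouping also follows the labelled shRNA, and a response that depends on the shRNA sets no bound on other genes. The labels give 1 shRNA and 1 ligand per group.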

How the results depend on the processing

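The fit without the 4 libraries labelled shctrl IL-1 and shp65 EGF was chosen only after the data were seen; the other alternatives were planned. Of 162 gene results checked, which include those named in the text, 0 changed sign in any alternative. Of the 158 that were called, 123 kept the call in all and 35 lost it in at least 1, most of them knockdown effects in untreated cells. Of the 4 that were not called, ICAM1 after IL-1 in shp65 cells gained a call with no filter. Counts of genes higher and lower stayed within 1.5 times with RLE factors for all 10 contrasts. Library totals moved 1, to 3005 genes lower in the libraries labelled shp65 EGF; the cause was not tested. For IL-1 in shp65 cells the counts were 1045 and 466 with no filter, 1050 and 447 with DESeq2, 325 and 84 in a fit of only the groups compared, and 263 and 35 without the 4 libraries. For the knockdown effect in untreated cells they were 363 and 424, 325 and 450, 1 and 0, and 25 and 20 in the same order. For EGF against the libraries labelled shctrl IL-1 they were 256 and 398, 199 and 376, and 0 and 5 in the first 3 settings. The fits of fewer groups have fewer libraries to estimate the spread. For the untreated knockdown comparison they also leave out groups with closer replicates, which lend their spread to the main fit. Which of these lowered the counts was not tested. For no filter and DESeq2 the cause was not tested either. In these fits a gene list or a count near the threshold rests on 2 libraries per group, and the lone library of a group is assumed to vary like the others when its partner is left out. With the knockdown effect under the ligand in place of the response difference, p65-dependent genes numbered 4572 for EGF and 4776 for IL-1; the cause was not tested. With an estimated correlation the gene lists past the threshold numbered 1 and 0 for the groups labelled shctrl EGF and shctrl IL-1, 8 and 7 for those labelled shp65 EGF and shp65 IL-1, 0, 7 and 1 for the knockdown effect in the groups labelled untreated, EGF and IL-1, 8 and 0 for the differences in the EGF and IL-1 responses, and 0 for EGF against the libraries labelled shctrl IL-1; that test allows for correlated genes.

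Leaving out each library in turn gave, for genes higher and lower, 2806 to 3926 and 2398 to 3664 (labelled shctrl EGF), 2713 to 3990 and 2110 to 3528 (labelled shctrl IL-1), 1197 to 2435 and 676 to 2129 (labelled shp65 EGF), and 117 to 844 and 6 to 376 (labelled shp65 IL-1). The knockdown effect gave 7 to 227 and 16 to 283 in untreated cells, 1975 to 3096 and 2046 to 3317 between groups labelled EGF, and 1725 to 3104 and 2055 to 3464 between groups labelled IL-1. The response differences gave 1033 to 1701 and 985 to 1748 for EGF and 877 to 1637 and 956 to 2056 for IL-1, and EGF against the libraries labelled shctrl IL-1 gave 0 to 105 and 10 to 192. The p65-dependent genes numbered 1588 to 2666 for EGF and 1650 to 3353 for IL-1.

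With the replicate number as a replicate block, counts stayed within 1.5 times: 3645 and 3542 for EGF in shctrl cells, 3632 and 3336 for the libraries labelled shctrl IL-1, 2292 and 1772 for those labelled shp65 EGF and 663 and 216 for IL-1 in shp65 cells, 130 and 184, 2954 and 3028, and 2930 and 3178 for the knockdown effect in the groups labelled untreated, EGF and IL-1, 1825 and 1586, and 1571 and 1599 for the differences as labelled in the EGF and IL-1 responses, and 68 and 167 for EGF against the libraries labelled shctrl IL-1. The block gave 2618 and 2894 p65-dependent genes, 2995 and 2648 genes shared by both responses, and 9, 8, 16, 12, 10, 14, 14, 13, 13 and 11 gene lists in the 10 contrasts. Among the named genes only CFB in untreated cells lost its call under the block. Over 15 pairs of groups the correlation of the deviations of same-numbered libraries ran from −0.33 to 0.339, with 6 above 0.1. For shctrl and shp65 groups with the same treatment it was 0.171 in untreated, 0.175 in EGF and 0.339 in IL-1 groups, a hint from the data and not the design. As not every pair of groups passed 0.1, the numbers were not taken to pair the libraries. For the peak results no paired analysis was possible, because they come from no test to which a replicate block could be added.

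For peaks in untreated, EGF and IL-1 lists, a −log10 q of at least 5 left 1042, 1179 and 3446, and peaks found in both replicates 144, 367 and 417. One replicate in place of the merged list gave 231 to 721, 519 to 1095 and 486 to 9750. Shared peaks were, for untreated in EGF, 473 with the q limit, 89 in both replicates, 490 with 50% reciprocal overlap and 103 to 493 in single replicates. They were 579, 90, 345 and 128 to 647 for untreated in IL-1, 460, 88, 490 and 109 to 490 for EGF in untreated, and 1105, 236, 911 and 259 to 1049 for EGF in IL-1. They were 559, 92, 345 and 153 to 598 for IL-1 in untreated and 1082, 235, 911 and 264 to 969 for IL-1 in EGF. Reciprocal overlap left 74, 200 and 12 peaks shared between replicates in untreated, EGF and IL-1 lists. The q limit, the need for both replicates and reciprocal overlap keep fewer peaks by construction; for the single-replicate lists the cause was not tested here. The test of peaks near responding genes and its 4 alternatives were not run. Depth limits calls of genes near the floor of 3 counts, and the depth of the ChIP-seq libraries is unknown.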

Other observations

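The tests on the peak lists in this part were chosen only after the lengths of the lists were seen.

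Further gene lists gave mixed results for IL-1 in shp65 cells, and of those given here only the EGF family ligands passed the threshold with an estimated correlation. Of 26 cholesterol genes 9 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 6.21e-10, and adjusted p = 0.248 with an estimated correlation). Of 8 EGF family ligands 4 rose and 1 fell, the same adjusted over the list alone (adjusted p = 2.04e-05, and adjusted p = 0.0498 with an estimated correlation). Protease and migration genes had 11 of 28 higher and 0 lower (13 and 2 adjusted over the list alone; adjusted p = 2.6e-09, and adjusted p = 0.184 with an estimated correlation). Of 35 cell cycle genes edgeR called 0, over all genes and adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 and 0 by DESeq2. Of 29 interferon-stimulated genes 3 rose (7 adjusted over the list alone, with 1 lower; median log2 fold change −0.02, mean 0.16; adjusted p = 0.162).

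The IL-1 peak list of replicate 1 was far longer than that of replicate 2. Fewer reads or weaker enrichment in IL-1 replicate 2 at the same sites and a step shared by the replicate 1 samples that brought peaks of its own cannot be told apart. The peaks of replicate 1 that replicate 2 also listed had a median percentile of 96.0 by fold enrichment within the replicate 1 list, and 99.6% of the peaks of EGF replicate 2 overlapped that list, but either explanation allows both values. Only 12 peaks were shared between the IL-1 replicates with 50% reciprocal overlap, against 200 for EGF and 74 for untreated cells. Median widths in replicates 1 and 2 were 302 and 114 bp for IL-1, 126 and 133 bp for EGF, and 123 and 418 bp for untreated cells. An IL-1 peak of 114 bp inside one of 302 bp cannot pass 50% reciprocal overlap. These are medians of whole lists, and the widths of the overlapping peaks were not compared. In untreated cells, where the medians lay further apart, 74 of the 131 replicate 2 peaks that overlapped replicate 1 passed, against 12 of 435 for IL-1. Width is therefore not shown to account for the low count for IL-1. That count alone does not show that the sites differ either. The ChIP-seq depth is unknown, and no biological explanation was tested.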
